A study of Homo sapiens with 5 samples.

How the data were processed

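RNA from 5 established human pancreatic cell lines was measured on 5 one-colour Affymetrix expression arrays, 1 array per line. The lines were PANC1, HPAF1, SU86.86, L3.6 and HPDE. Per the labels' protocols, cells were grown as the supplier of the lines recommended, total RNA was taken up on silica columns, and biotin-labelled target was made with a single-cycle kit of the array's maker. The source label calls all 5 lines pancreatic cancer lines. HPDE is known in the field as an immortalised line of normal pancreatic duct epithelium, which is background and not a statement of the labels.

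The deposited table holds linear intensity values for 54675 probe sets on each array. How the authors summarised, scaled or background-corrected these deposited intensities is not given in the sources used here. The array medians lay between 137 and 143 intensity units, and the log2 medians differed by 0.04, within the tolerance of 0.25 set for leaving the values as deposited. No further normalization was therefore applied. On 9 spike-in control probe sets the standard deviation between arrays had a median of 0.11 and a maximum of 0.14 on the log2 scale. That spread covers hybridisation and scanning, not growth, harvest or labelling of a second culture. HPDE had the highest mean intensity on each of the bioB, bioC, bioD and cre spike-in controls. For cre it was 19109, against 15586 to 17797 on the other arrays. The number of arrays, 1 per line, limits the precision of every value.

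Intensities were transformed as log2(value + 71.1), the added constant being the 25th percentile of the positive values. Differences on this scale understate the fold change of dim genes, and the added constant also narrows the spread between lines near background. Of 44 genes past the limma threshold, 22 had the other 4 lines below the level filter, so their SE and p rest on background readings. The 62 control probe sets of the array's maker were left out of the gene table. Of the probe sets, 41091 carried 1 gene symbol, 1801 carried several and 11777 were not listed in the annotation used. No gene was named from a probe set with several symbols. Of those with 1 symbol, 41037 were matched to current symbols through a RefSeq gene table for the assembly GRCh38.p14, and 54 kept the older symbol. That table was also used for the order of genes along chromosomes, without coordinates. For each of 19775 genes the probe set with the highest mean was kept. Genes whose highest value reached the median of all probe sets, an intensity of 140 after the transformation was undone, were retained, leaving 14894 genes.

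Each line was compared with the mean of the other 4 using limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the 14894 genes and a threshold of 0.05. All tests were two-sided. The fit has 3 residual degrees of freedom and assumes that the lone line varies as the other 4 do. These p-values measure the spread between different cell lines, not between cultures of a line. Each line was also set against HPDE. Those differences have 1 array on each side and no replicate check, so they were described by size alone, at 2-fold or more, with no p-value. Similarity between lines was measured by the Pearson correlation and by the median absolute log2 difference across genes, for the 10 pairs of lines. Genes are not independent replicates, so no p-value was attached.

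In all, 37 gene lists were fixed before the data were examined, 5 of them markers of other cell types and others holding control genes. The median difference of a list's measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was described as outside the random range when its median lay below the 0.5 or above the 99.5 percentile. That limit was set after the data were seen. The percentile describes these arrays and is not a replicate test, and members of a list vary together, so the random lists understate how often a list would stand apart. Genes were named by a rule fixed in advance. For HPDE it took the 10 genes with the widest gap above and the 10 with the widest gap below the other 4 lines. For every other line it took 5 above and 3 below. For each line minus HPDE it took the 3 highest and 3 lowest genes. It also took up to 4 members per list with the widest range, and a fixed set of 6 genes always named. Of these 6, 4 are reported. The others had no probe set of their own here and are not reported. Some further genes that passed the limma threshold are named as well, chosen after their values were seen. Among the genes named for a line, no probe set above the level filter went the opposite way to the one used. Of the 28 with several such probe sets, 7 had only 1 that differed by 2-fold or more, so their large differences rest on that probe set. The smallest difference on another probe set was 0.52 for ITPR2 and -0.33 for KRT7 in PANC1, -0.12 for BASP1 in HPAF1, -0.37 for GDF15 in SU86.86, and 0.66 for SPARC and -0.59 for HOXB6 in HPDE. For VIM minus HPDE it was 0.82 in PANC1 and 0.29 in L3.6. Genes named only from a list or from the fixed set, such as CDKN2A and SMAD4, were not checked in this way.

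The alternatives fixed in advance were quantile normalization, median centring, the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, no level filter, a stricter level filter at the 75th percentile, a floor at the 25th percentile, limma's trend and robust options, 4-fold in place of 2-fold, and leaving out each line in turn. A log2 scale without the added constant, counts without HPAF1 and the scan of neighbouring genes were added after the data were seen. The fit was tested on simulated data for HPDE against the other 4 lines over 14894 genes. Of 50 genes changed by each size, 0 were recovered at a log2 difference of 1, 15 at 2, 33 at 4 and 42 at 6, with 3 false calls. In the same simulation of the list test, 0 of 40 unshifted lists and 40 of 40 lists shifted by 0.5 stood above the random range. Simulated genes varied independently and these lists were drawn at random. The result therefore says nothing about how often a list whose members vary together would stand apart. Values were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.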

Results

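Expression was profiled in 5 human pancreatic cell lines. PANC1, HPAF1, SU86.86 and L3.6 derive from pancreatic carcinomas, and HPDE is an immortalised line of pancreatic duct epithelium. There was 1 array per line and no replicate culture, so no value for a line carries an error of its own. Standard errors given with a difference are those of the limma fit and rest on the spread between the other 4 lines. Levels are log2 intensities and differences are log2 differences. Members of a gene list counted as higher or lower differed by at least 2-fold. The array medians ranged from 137 in SU86.86 to 143 in HPAF1, and between 12892 genes in HPDE and 13237 in L3.6 lay above the level filter. The labels state no question beyond the profiling of these lines. The comparisons made were the resemblance of the lines, each line against the other 4, and each carcinoma line against HPDE.

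By correlation, SU86.86 and L3.6 resembled each other most, and PANC1 and HPAF1 least. The correlation across 14894 genes was 0.886 for the first pair and 0.776 for the second, with 1584 and 2914 genes differing by 2-fold or more. By median absolute log2 difference the nearest pair was instead PANC1 and L3.6 (0.25). That difference was 0.27 for PANC1 and SU86.86, and 0.29 for SU86.86 and L3.6. PANC1 and HPAF1 were farthest by this measure too (0.3441), close to HPAF1 and HPDE (0.3436). Genes that parted PANC1 from HPAF1 included VIM, an intermediate filament of mesenchymal cells, at 14.74 in PANC1 and 9.52 in HPAF1. They also included TSPAN8, a tetraspanin of gastrointestinal epithelium, at 6.68 in PANC1 and 14.33 in HPAF1, and KRT7, a keratin of simple epithelia, at 7.51 and 13.34. HPDE correlated with the carcinoma lines between 0.803 for PANC1 and 0.849 for L3.6. The median over the 10 pairs was 0.838. HPAF1 had 607 genes at least 2-fold apart from every other line, PANC1 454, HPDE 442, SU86.86 220 and L3.6 185.

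HPDE was set apart by genes of basal and squamous epithelium. KRT14, a keratin of basal keratinocytes, stood at 13.64 in HPDE and between 6.99 and 7.44 in the carcinoma lines, a difference of 6.39 (SE 0.25, limma adjusted p = 0.0378). KRT16, a keratin of activated keratinocytes, was higher by 4.53 (SE 0.23, limma adjusted p = 0.0393). CCND2, a D-type cyclin, was higher by 4.63 (SE 0.20), and SPARC, a secreted matrix glycoprotein, by 3.96 (SE 0.19), both at a limma adjusted p of 0.0378. These 4 genes were the only ones past the limma threshold for HPDE, all higher. For each of them the other lines lay below the level filter, so the SE and p rest on background readings, and 0 passed without the added constant. In HPDE 1226 genes had an unadjusted p under 0.05 against 744.7 that chance would give. With PANC1, HPAF1, SU86.86 or L3.6 left out of the fit, 0 genes passed the limma threshold, and 1068, 1771, 1094 and 1046 genes had an unadjusted p under 0.05.

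Of 22 measured basal and squamous genes, 19 were at least 2-fold higher in HPDE than in the mean of the other lines and 0 were lower. Their median difference was 3.36, above all 10000 random lists. Of the 22, 12 passed when adjusted over the list alone and 2 when adjusted over all genes. CSTA, an inhibitor of cysteine proteases in the cornified envelope, reached 13.46 in HPDE, 10.30 in L3.6 and 6.80 in PANC1. S100A8, a subunit of calprotectin, reached 12.80 in HPDE and at most 7.87 in SU86.86. The cornified envelope precursors SPRR1B and SPRR1A stood at 12.57 and 11.91 in HPDE. The list was not uniform across the carcinoma lines. KRT5, the partner of KRT14 in basal cells, was at 12.41 in L3.6 and 9.68 in SU86.86 but 7.26 in HPAF1, and the calcium-binding protein S100A2 was higher in L3.6 (14.42) than in HPDE (12.84). Among other genes high in HPDE, the desmosomal protein PKP1 reached 11.66 and the lysosomal membrane protein LAMP3 reached 11.58. Pancreatic duct markers were not high in HPDE. The 16 measured had a median of -0.37 there, below the random range, with 4 at least 2-fold lower and 0 higher. Without HPAF1 that median was -0.24. In HPAF1 and SU86.86 the duct markers had medians of 0.56 and 0.43, above the range.

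**Figure D1:**
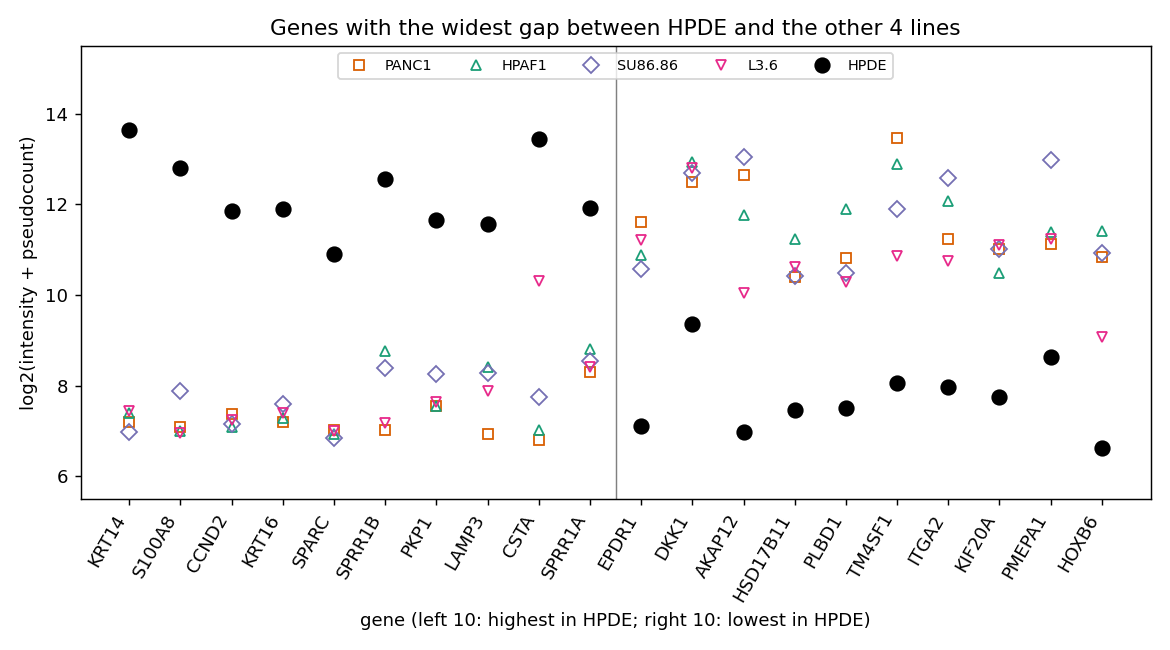
Log2 intensity in each of the 5 lines (1 array per line, no error bars) for the 20 genes named for HPDE, the 10 with the widest gap above and the 10 with the widest gap below the other 4 lines. HPDE lies apart from the other lines at each gene, from KRT14 at 13.64 in HPDE and at most 7.44 elsewhere to HOXB6 at 6.61 in HPDE and at least 9.06 elsewhere.

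Interferon-stimulated genes were high in HPDE, intermediate in HPAF1 and lower in SU86.86, L3.6 and PANC1. Of 29 measured members, 26 were at least 2-fold higher in HPDE than in the mean of the other lines and 0 were lower, with a median difference of 2.99, above all 10000 random lists. For HPDE 0 members passed limma, adjusted over all genes or adjusted over the list alone, while 14 had an unadjusted p under 0.05. Against each line alone, 28 members were at least 2-fold lower in PANC1 than in HPDE, 26 in L3.6, 25 in SU86.86 and 19 in HPAF1. In all 4 lines together 18 were lower, and 24 were with HPAF1 left aside. MX1, a GTPase that restricts viruses, stood at 13.18 in HPDE, 11.78 in HPAF1, 8.43 in SU86.86, 7.19 in L3.6 and 6.91 in PANC1. The ubiquitin-like modifier ISG15 ran from 14.45 in HPDE to 8.88 in L3.6, and BST2, which tethers budding virions, from 12.40 in HPDE to 6.74 in PANC1. In HPAF1 5 members were higher than in HPDE by any amount, among them IFI27 at 14.20 against 13.86. SU86.86 against the other lines had a median of -0.94, below all 10000 random lists, with 12 of 29 at least 2-fold lower and 1 higher. That median was -1.48 without PANC1 and, within the random range, -0.20 without HPDE.

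HPDE had the lowest levels of mitotic genes. Of 25 proliferation genes, 24 were at least 2-fold lower in HPDE than in the mean of the other lines and 0 were higher, a median difference of -1.92, below all 10000 random lists, and 2 passed limma when adjusted over the list alone and 0 when adjusted over all genes. The mitotic kinesin KIF20A stood at 7.76 in HPDE and between 10.48 and 11.10 elsewhere. AURKB, a kinase of the chromosomal passenger complex, was at 8.27 in HPDE, 9.78 in HPAF1 and 11.45 to 11.73 in the others. HPAF1 was the nearest to HPDE, with 8 members at least 2-fold above it, against 24 in PANC1, 24 in SU86.86 and 25 in L3.6. Genes of DNA replication were low in both HPDE and HPAF1. Of 26 members, 16 had their lowest level in HPAF1 and 10 in HPDE. The median for HPDE was -0.87, with 12 members at least 2-fold lower, and -1.32 without HPAF1, with 17 lower, and 0 passed limma in HPDE when adjusted over the list alone. TYMS, which makes thymidylate, stood at 8.69 in HPDE, 9.96 in HPAF1 and 12.30 to 13.58 in the others, and the ribonucleotide reductase subunit RRM2 at 8.81, 11.18 and 13.21 to 13.34. Against HPAF1 alone the replication list's median was -0.18 for HPAF1 minus HPDE, within the random range. Among 20 control housekeeping genes, 4 were at least 2-fold lower in HPDE, among them the tubulins TUBB and TUBA1B at 12.12 and 13.12, with a median of -0.34 inside the random range, and 3 passed limma when adjusted over the list alone. The 27 ribosomal protein genes had a median of 0.03.

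**Figure D2:**
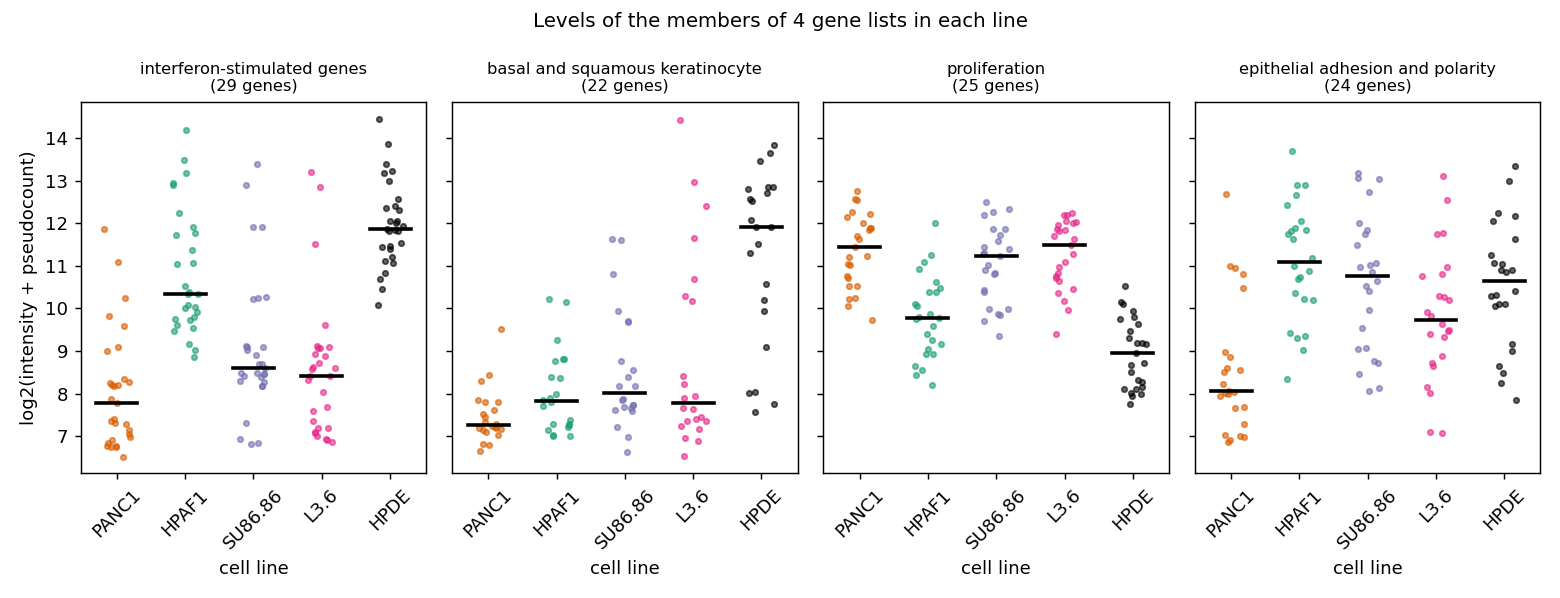
Log2 intensity of every measured member of 4 gene lists in each line (points, 1 array per line), with the median of the members as a bar: interferon-stimulated genes (29), basal and squamous genes (22), proliferation genes (25) and epithelial genes (24). HPDE has the highest median for the interferon and basal lists (11.85 and 11.91) and the lowest for proliferation (8.94), and PANC1 the lowest for the epithelial list (8.05).

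The cyclin-dependent kinase inhibitor CDKN1A stood at 12.92 in HPDE and 9.37 in L3.6, and PHLDA3, an inhibitor of AKT signalling, at 11.40 in HPDE and at most 9.51 elsewhere. The list of p53 targets, 22 measured, had a median of 0.66 in HPDE, above the random range. Of its members 4 were at least 2-fold higher and 1 lower, and 0 passed limma when adjusted over the list alone. Of 17 HOX genes, 8 were at least 2-fold lower in HPDE and 0 at least 2-fold higher, with a median of -0.71 that became -0.42 without PANC1, -0.34 without SU86.86 and -0.26 with no level filter, but -1.06 without HPAF1 and -1.14 with the stricter level filter. HOXB6 was at 6.61 and HOXC6 at 6.68 in HPDE, against at least 9.06 and 8.86 in the other lines. Further genes low in HPDE were DKK1, a secreted WNT antagonist, at 9.36 against 12.49 to 12.93, and ITGA2, a collagen receptor subunit, at 7.97 against at least 10.76. TM4SF1, a surface antigen of many carcinomas, was at 8.06 against at least 10.85, the scaffold protein AKAP12 at 6.98 against at least 10.05, and PMEPA1, a feedback inhibitor of TGF-beta signalling, at 8.64 against at least 11.13. The widest gaps below the other lines also included EPDR1 (7.10), HSD17B11 (7.46) and PLBD1 (7.50). The TGF-beta and BMP list had a median of -0.69 in HPDE, which was -0.15 and within the random range without HPAF1, and -0.42 without SU86.86. Without probe sets that can match several transcripts it was -0.11, also within that range, and with the mean of all probe sets -0.41. The medians of the classical signature (-0.77, or -1.58 with the stricter level filter) and of the NRF2 list (-0.68) likewise became -0.15 and -0.21 without HPAF1, both within the random range, and the NRF2 median was -0.17 and within the range without probe sets that can match several transcripts. Of these HOX, TGF-beta, classical and NRF2 lists 0 members passed limma in HPDE when adjusted over the list alone.

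Setting each carcinoma line against HPDE gave 2640 genes at least 2-fold apart in PANC1, 2538 in HPAF1, 2407 in SU86.86 and 2255 in L3.6. The same direction was shared by all 4 lines for 144 genes higher and 298 lower than HPDE. KRT14, CSTA and MX1 were among the shared lower genes, DKK1, KIF20A and HOXB6 among the shared higher ones. HPDE is 1 array common to all 4 differences, so part of this sharing may arise from it. Lists independent of each other would share 0.541 and 0.848 genes, while an average line of the 5, taken as the common reference, stood at least 2-fold above every other for 235.6 genes and below for 146. Without PANC1 220 genes were higher, and without HPAF1 389 were higher and 472 lower.

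PANC1 had low levels of many epithelial genes and the highest level of VIM. MAL2, a protein of apical transport in polarised epithelia, stood at 7.03 in PANC1 and between 12.55 and 13.04 elsewhere, a difference of -5.78 (SE 0.28, limma adjusted p = 0.0380). The monocyte chemoattractant CCL2 was higher by 5.33 (SE 0.20, adjusted p = 0.0294), the inositol trisphosphate receptor ITPR2 by 5.55 on 1 of its 3 probe sets (SE 0.25, adjusted p = 0.0364) and the RNA-binding protein RBM24 by 4.14 (SE 0.23, adjusted p = 0.0474). Those 4 genes passed limma. For CCL2 and RBM24 the other lines lay below the level filter, so the SE and p rest on background readings, and without the added constant CCL2 passed (adjusted p = 0.0324) and RBM24 did not (0.0675). With any of the other lines left out, HPAF1, SU86.86, L3.6 or HPDE, 0 passed, and 860, 884, 878 and 851 genes had an unadjusted p under 0.05 (828 with all lines, against 744.7 by chance). ITPR2 also fell short of the limma threshold without the added constant, while MAL2 still passed. CDH1, the epithelial cadherin, was at 8.61 in PANC1, 9.92 in L3.6 and 12.73 to 13.34 in the others. ESRP1, a splicing factor of epithelial cells, was at 6.88 against at least 10.77, and the small GTPase RAB25 was at 6.91 in PANC1 and 7.09 in L3.6. Of 24 epithelial genes, 15 were at least 2-fold lower in PANC1 and 0 higher, with a median of -1.89, below all 10000 random lists; 5 passed when adjusted over the list alone and 1 over all genes. The 24 mesenchymal genes had a median of 0.00 in PANC1, within the random range, although VIM itself reached 14.74. Without SU86.86 that median was 0.28, above the range.

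Other lists were also outside the random range in PANC1, some low and some high. Adjusted over the list alone, 2 interferon-stimulated genes, 1 gene of the basal-like signature and 1 cytokine, CCL2, passed limma, and 0 of the MHC class I, HOX and proliferation lists. Interferon-stimulated genes had a median of -2.02, with 24 of 29 at least 2-fold lower. The MHC class I and antigen processing list had a median of -1.01, with 8 of 15 at least 2-fold lower, HLA-B at 11.12 against at least 12.33. Without probe sets that can match several transcripts that median was -0.39, within the random range. The basal-like signature had a median of -2.14, or -1.24 without HPDE and -1.40 with the mean of all probe sets, and KRT7 and the annexin ANXA3 (6.83 against at least 11.36) were the other genes with the widest gaps below. Cytokines and chemokines had a median of -1.17, or -0.46 without SU86.86 and -0.38 without probe sets that can match several transcripts, with CXCL8 at 6.89. CCL2 was the only one of the 23 at least 2-fold higher in PANC1. HOX genes had a median of 1.09 in PANC1, or 0.70 without HPDE, 0.72 with the mean of all probe sets, 0.41 without probe sets that can match several transcripts and 0.43 with no level filter, with 9 of 17 at least 2-fold higher, and HOXC6 reached 11.53. Proliferation genes had a median of 1.02, or 0.67 without HPDE, with 13 of 25 at least 2-fold higher. Against HPDE alone the highest genes in PANC1 were VIM (6.72), the disulfide isomerase AGR2 (5.95) and ITPR2 (5.76), and the lowest were IFI27 (-6.72), CSTA (-6.65) and S100A14 (-6.57). PPP1R14A (12.59) and RFLNB (12.36) also lay far above the other lines.

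HPAF1 had the most genes past the limma threshold. LYZ, lysozyme, stood at 13.57 in HPAF1 and at most 6.85 in the other lines, a difference of 6.80 (SE 0.17, limma adjusted p = 0.0063), or 8.30 without the added constant (SE 0.25, adjusted p = 0.0095). CDH17, the liver-intestine cadherin, stood at 12.54 against at most 7.08 (SE of the difference 0.17, limma adjusted p = 0.0079), and KRT20, a keratin of intestinal and gastric epithelium, was higher by 5.30 (SE 0.20, limma adjusted p = 0.0094). At the same adjusted p were LGALS4, an intestinal galectin, higher by 5.33, the microvillus protein VIL1 by 4.25, the mucin-type glycosyltransferase GCNT3 by 4.72, TM4SF4 by 4.78 and the kallikrein KLK6 by 4.80. In all, 36 genes passed limma, 32 higher and 4 lower. For 16 of the 36, LYZ, CDH17, KRT20, LGALS4 and VIL1 among them, the other lines lay below the level filter, so the SE and p rest on background readings. Without the added constant, which can also change the probe set kept for a gene, 11 of these 16 still passed, VIL1 not among them. The lower genes were PFN2 (-4.06), SGCE (-3.32), SPART (-3.25) and ADGRL2 (-2.36). With PANC1, SU86.86, L3.6 or HPDE left out of the fit, 0 passed, and 1358, 1461, 1331 and 1991 genes had an unadjusted p under 0.05 (1497 with all lines, against 744.7 by chance). BASP1 (6.95 against at least 11.75), the gap junction protein GJA1 (6.56 against at least 10.72) and IGFBP7 (7.67 against at least 11.65) were far below the other lines without passing.

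The classical pancreatic tumour signature had a median of 1.24 in HPAF1, or 4.31 with the stricter level filter, with 12 of 22 members at least 2-fold higher and 0 lower; 9 passed when adjusted over the list alone and 6 over all genes. TSPAN8 reached 14.33 in HPAF1 and CEACAM6, a carcinoembryonic antigen relative, 14.13. The list of endoderm and gastrointestinal transcription factors had a median of 0.38 over 15 genes, above the random range, and 0.86 without PANC1, 0.70 without SU86.86 and, within the range, 0.24 without HPDE and 0.55 with the stricter level filter. It was 0.58 with the mean of all probe sets and 0.62 without the added constant, both above the range. Mucins and secreted mucosal proteins had a median of 0.17 over 21 genes, within the random range, with 8 at least 2-fold higher, 0 lower and 5 past the threshold adjusted over the list alone. That median was 0.33 without L3.6, 0.31 without HPDE, 0.48 with the mean of all probe sets and 1.43 with the stricter level filter, each above the range. The CEA family and surface antigen list had a median of 0.85, with 5 of 19 past the threshold adjusted over the list alone, among them MSLN, mesothelin, higher by 2.96. Aldehyde dehydrogenases and retinoid genes had a median of 1.33, with 11 of 20 at least 2-fold higher, 4 past the threshold adjusted over the list alone and 2 over all genes. ALDH1A1 was higher by 3.39 (limma adjusted p = 0.0160), and the mitochondrial enzyme ALDH2 stood at 13.06 against at most 11.27. The NRF2 and glutathione list had a median of 1.05, or 0.32 without probe sets that can match several transcripts, with 11 of 22 members at least 2-fold higher. The aldo-keto reductase AKR1C3 stood at 13.20 against at most 9.94. AKR1B10 was higher by 3.23 and passed limma over all genes, but not without the added constant.

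Genes of cholesterol and fatty acid synthesis had a median of 1.06 in HPAF1, with 10 of 20 at least 2-fold higher and 5 past the limma threshold adjusted over the list alone, 0 over all genes. The desaturase SCD was at 13.66 and MSMO1, a sterol oxidase, at 12.52. Epithelial genes had a median of 1.15, which was 0.61 without PANC1, and CLDN4, a tight junction claudin, reached 12.04. Interferon-stimulated genes had a median of 1.05, with 15 of 29 at least 2-fold higher. That median was 2.11 without HPDE, 0.65 without PANC1 and 0.64 without L3.6. Replication genes had a median of -1.16, with 17 of 26 at least 2-fold lower, and proliferation genes had a median of -0.92, or -1.48 without HPDE, with 11 of 25 at least 2-fold lower. Adjusted over the list alone, 1 epithelial and 1 replication gene passed limma, and 0 interferon-stimulated and 0 proliferation genes. Leukocyte markers had a median of 0.41 over 9 genes in HPAF1, above the random range. LYZ is a member of that list and of the classical signature. The median was 0.60 without SU86.86 and 0.68 without the added constant, still above the range. It was 0.31 without PANC1, 0.30 without L3.6 and 0.21 without HPDE, each within the random range, and it was within that range under each probe set, filter and floor setting tried. Against HPDE alone the highest genes were TSPAN8 (7.74), LYZ (6.83) and CEACAM6 (6.53), and the lowest KRT5 (-6.57), CSTA (-6.44) and KRT14 (-6.25).

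SU86.86 had the highest levels of several cytokines and secreted proteins. IL1A, an alarmin of the interleukin-1 family, stood at 13.06 in SU86.86 and 11.99 in HPDE, and at most 8.30 in the other lines. The neutrophil chemoattractants CXCL5 and CXCL8 reached 13.36 and 12.15 in SU86.86. CST6, a secreted cysteine protease inhibitor, was at 13.22 against at most 8.67, the collagen COL8A1 at 11.12 against at most 7.34, the pentraxin PTX3 at 11.54 against at most 8.28 and INHBA, a subunit of activin, at 11.25 against at most 8.19. TMEM200A, at 10.15 against at most 6.67, had the lowest adjusted p, 0.181. In limma 0 genes passed, and 557 had an unadjusted p under 0.05, fewer than the 744.7 that chance would give. With limma's trend option 2 passed.

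Of 23 cytokines and chemokines, 13 were at least 2-fold higher in SU86.86 and 1 lower, with a median of 1.40, or 2.47 with the stricter level filter, above all 10000 random lists; 5 passed limma when adjusted over the list alone. MHC class I and antigen processing genes had a median of 0.96, or 0.59 without probe sets that can match several transcripts, with 7 of 15 at least 2-fold higher, and HLA-B was at 13.94. MHC class II genes had a median of 0.92 over 10 genes, HLA-DRA being at 9.52 against at most 8.04. That median was -0.01 without probe sets that can match several transcripts and 1.34 with the stricter level filter, both within the random range. Mesenchymal genes had a median of 0.71, or 0.34 without HPDE, 0.31 without probe sets that can match several transcripts and 1.56 with the stricter level filter, with 10 of 24 at least 2-fold higher. Laminins and integrins had a median of 0.68, LAMB3 standing at 12.31. Genes of cholesterol and fatty acid synthesis had a median of -0.64, or -0.41 without HPAF1, and SCD stood at 10.25 against at least 11.93. Adjusted over the list alone, 4 MHC class II and 4 mesenchymal genes passed limma, and 0 of the MHC class I, laminin and cholesterol lists. The genes farthest below the other lines were CRNDE, a long noncoding RNA (6.44 against at least 10.05), GDF15, a stress-induced cytokine (7.12 against at least 9.34), and KLHL9 (6.89 against at least 9.39). Against HPDE alone the highest were CXCL5 (6.98), AKAP12 (6.07) and CST6 (5.26), and the lowest KRT14 (-6.66), CSTA (-5.71) and BST2 (-5.55).

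L3.6 had the fewest genes at least 2-fold apart from every other line. KRT13, a keratin of stratified epithelium, stood at 12.97 in L3.6 and at most 7.76 elsewhere, a difference of 5.52 (limma adjusted p = 0.246). The glycoprotein hormone STC1 was at 10.78 against at most 7.64, and NLRP2 (9.74), the peptidylarginine deiminase PADI3 (10.22) and CT83 (9.68) were the other genes with the widest gaps above. The interferon-induced genes IRF7 and MX2 were at 7.01 and 6.94 against at least 9.82 and 10.08, and CRABP2, which carries retinoic acid, was at 8.04 against at least 10.86. In limma 0 genes passed, and 502 had an unadjusted p under 0.05, also below the 744.7 of chance. Proliferation genes had a median of 1.04, with 16 of 25 at least 2-fold higher, or 0.66 without HPDE. Replication genes had a median of 0.97, with 13 of 26 at least 2-fold higher, or 0.63 without HPDE and 0.60 without HPAF1. Interferon-stimulated genes had a median of -1.17, with 16 of 29 at least 2-fold lower and 1 higher, which became -0.43 without HPDE. MHC class I and antigen processing genes had a median of -0.52, or -0.95 without PANC1 and, within the random range, -0.41 without SU86.86. Adjusted over the list alone, 1 replication gene and 1 interferon-stimulated gene passed limma, and 0 of the proliferation and MHC class I lists. Against HPDE alone the highest were the calcium-binding protein CALB1 (5.83), VIM (5.82) and CXCL5 (5.28), and the lowest IFI27 (-6.67), KRT14 (-6.20) and MX1 (-5.98).

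**Figure D3:**
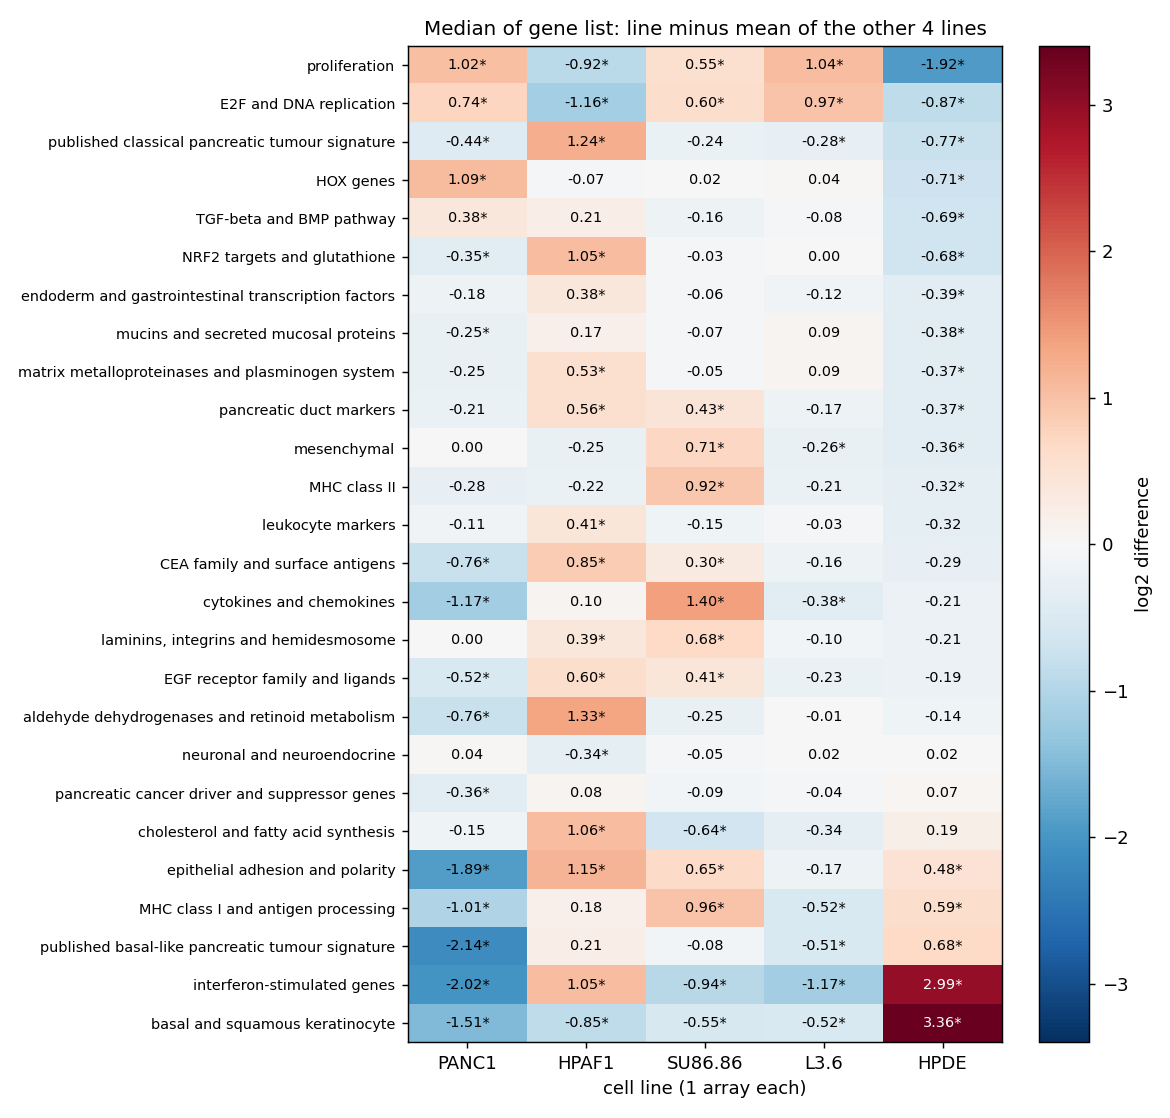
Median log2 difference of gene lists (rows) between each line and the mean of the other 4 (columns), colour and printed value; an asterisk marks a median outside the range of 10000 random lists matched on expression. The basal and interferon lists in HPDE, at 3.36 and 2.99, are the highest values shown and the basal-like signature in PANC1, at -2.14, the lowest. Lists within the range in every line are left out, and not every list outside it is shown.

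Of the tumour suppressors always named, CDKN2A, which encodes inhibitors of the cyclin D kinases and of MDM2, varied most. It stood at 13.45 in HPAF1, 13.17 in HPDE and 12.47 in L3.6, and at 7.97 in PANC1 and 8.02 in SU86.86. Its neighbour CDKN2B was at 6.53 in PANC1 and 6.59 in SU86.86 against 11.48 in HPAF1. SMAD4, the shared mediator of TGF-beta and BMP signals, had its lowest level in SU86.86 (8.63) and its highest in HPDE (10.36). The kinase gene AKT2 was at 12.84 in PANC1, 11.53 in SU86.86 and at most 9.81 in the others. These differences were described by level and none was past the limma threshold.

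Over all lists, 75 of 185 medians against the other lines and 53 of 148 medians against HPDE lay outside the random range. Lists of unrelated genes would give 1.85 and 1.48. Members of a list vary together and the comparisons share arrays, so these numbers are not what chance would give here. Hedgehog pathway genes (8 measured) and markers of acinar (7), islet (5) and endothelial cells (8) stayed within the range in every line under each setting run. The median of so short a list can be large without leaving the range, so this does not show that these genes were alike. With the stricter level filter it was 1.56 for acinar and 0.71 for endothelial markers in SU86.86. In the main setting WNT pathway genes, cancer-testis antigens and fibroblast markers also stayed within the range. Outside the range were WNT genes in HPDE without probe sets that can match several transcripts (-0.47) and cancer-testis antigens in PANC1 with the stricter level filter (2.42). With the mean of all probe sets fibroblast markers were outside it in PANC1 (0.56) and HPAF1 (-0.54). Single members still differed. MAGEA11, a cancer-testis antigen, was at 8.58 in L3.6 and at most 6.85 elsewhere, and the collagen COL1A2 at 9.91 in L3.6 and at most 7.59 elsewhere.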

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

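Every test of an explanation given here, and the rule of a 4-fold difference in opposite directions for single genes, was chosen only after the result it concerns had been seen.

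Against HPDE, some genes and 1 list went up in a carcinoma line and down in another, and these differences between lines were not tested. Genes of cholesterol and fatty acid synthesis had a median of 0.72 in HPAF1 and -0.56 in SU86.86. LCN2, an iron-scavenging lipocalin, differed from HPDE by 3.58 in SU86.86 and -3.51 in PANC1. DUSP4, a phosphatase of MAP kinases, differed by 2.39 in L3.6 and -2.75 in PANC1. The receptor ERBB3 differed by 2.03 in HPAF1 and -2.40 in PANC1, and AKR1C3 by 4.30 in HPAF1 and -2.26 in PANC1. Among 5464 probe sets above the level filter that carry no single gene name and entered no comparison, 1 was at least 4-fold above HPDE in all 4 carcinoma lines and 6 were at least 4-fold below.

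The raised interferon-stimulated genes of HPDE are not accounted for by array scaling, which would shift genes of equal level alike: random lists matched on expression had a median of 0.023 (SD 0.116) in HPDE, against 2.99 for these genes. RNA of leukocytes in the culture is also argued against, as the median of 17 leukocyte markers was -0.070 and the highest of them 0.36. What stays open is the state of the HPDE culture at harvest, because there was only 1 HPDE array and a passing interferon response cannot be told apart from a lasting property of the line. Cells were grown as the supplier of the lines recommended, and the growth medium of each line was not compared. Any difference in medium, and the immortalisation of HPDE, go with the line in every comparison with HPDE. They cannot be told apart from it. A biological difference between duct epithelium and carcinoma lines may also account for the raised interferon-stimulated genes. It was not tested, and HPDE is the only line of duct epithelium. The carcinoma lines were not alike in these genes: the median level was 10.35 in HPAF1 and 7.79 to 8.61 in the others, against 11.85 in HPDE.

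The low cell cycle genes of HPDE and HPAF1 are likewise not accounted for by scaling. Matched random lists had medians of -0.097 in HPAF1 and 0.052 in HPDE, against -0.92 and -1.92 for the proliferation genes. For HPAF1, degraded or 3'-biased RNA is argued against by an ACTB 3' to 5' ratio of 1.08, below the middle value of 1.11 in the remaining carcinoma lines. HPDE had the highest such ratio, 1.34, with a GAPDH ratio of 1.02 like the other arrays, so a contribution of RNA quality could not be excluded there. Growth rate and confluence at harvest were not measured here, and either might set these genes.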

How the results depend on the processing

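The log2 scale without an added constant, and the counts without HPAF1, were chosen after the data were seen; the other settings were fixed before. Of 803 values of named genes, 731 kept their direction and their side of the threshold. Of 2220 list medians, 2044 kept their side of the random range, 172 of them with a change of sign, while 96 medians went back inside the random range and 76 moved out of it. Leaving out 1 line, which leaves 2 residual degrees of freedom, gave 0 to 0 genes past the limma threshold for PANC1, HPAF1 and HPDE. No line had a call there, so this shows nothing about how stable the calls are. The differences of the called genes were then 0.987 to 1.01 times those with all lines for PANC1, 0.963 to 1.04 times for HPAF1 and 0.986 to 1.02 times for HPDE, as the small spread that led to their calling requires. Without probe sets that can match several transcripts, 0 genes passed for PANC1 and 1 for HPDE; with no level filter, 8 for PANC1 and 79 for HPAF1; with limma's trend option, 10 for PANC1, 104 for HPAF1 and 2 for SU86.86. A floor for dim values gave 56 for HPAF1. The mean of all probe sets gave 1 for HPDE, the stricter filter 1, and no added constant 2 for PANC1 and 0 for HPDE. At 4-fold in place of 2-fold, 772 genes differed from HPDE in PANC1, 610 in HPAF1, 573 in SU86.86 and 486 in L3.6, with 23 higher and 38 lower in all 4 lines. The count higher in all 4 lines was 92 with the mean of all probe sets and 88 without those that can match several transcripts, and leaving out a line gave 176 to 389 higher and 373 to 472 lower. For the similarity of the lines, the median correlation of 0.838 was 0.893 with no level filter and 0.740 with the stricter one. By correlation, the nearest and farthest pairs stayed the same. Among medians outside the random range, 4 changed sign. The basal list in SU86.86 (-0.55) was -1.14 without PANC1 and 0.16 without HPDE, the classical signature in L3.6 (-0.28) was -0.59 without HPDE and 0.11 without HPAF1, and the CEA list in SU86.86 (0.30) was -0.039 without PANC1 and 0.54 without L3.6; without probe sets that can match several transcripts MHC class II in SU86.86 was -0.0081. Apart from fewer lines or genes entering the fit, the cause was not tested. No paired analysis was possible because each line has 1 array. Genes near background, below an intensity of about 140, are limited by dim signal, and their differences are understated.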

Other observations

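All tests of neighbouring genes given here were chosen only after the levels of AKT2 and CDKN2A had been seen, and the split into the sides of a gene was added after the pooled value was known.

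Some differences between lines fell on genes that lie side by side. Medians of 10 consecutive measured genes were compared with those after 1000 shuffles of gene order over 14848 genes. In PANC1 a stretch of 34 genes from MRPS12 to PLD3, which holds AKT2, had a median of 1.63, with 20 genes at least 2-fold higher than in the other lines and a top window of 2.60 against a shuffle limit of 1.08. HPAF1 was low over part of the same stretch, from GMFG to LGALS13, where PANC1 enters the mean it is set against. Also in PANC1, 15 genes from INTS9 to TEX15, DUSP4 among them, had a median of -1.17 and a lowest window of -1.41 against a limit of -1.17. SU86.86 had 13 stretches with at least 1 window below its shuffle limit of -0.73, although the median of a whole stretch need not pass it. One ran over 15 genes from RPS6 to CAAP1, which include CDKN2A, CDKN2B, MTAP and KLHL9, with a median of -0.68, a lowest window of -1.68 and 6 genes at least 2-fold lower. Another ran over 18 genes from SKA1 to ATP8B1-AS1, which include SMAD4, with a median of -0.74 and 5 genes at least 2-fold lower. The nearest low stretches to it in gene order, with other genes between, were PIK3C3 to DYM (median -0.69) and TIMM21 to TSHZ1 (-0.97). Further out lay CABYR to GAREM1 (-0.48), DTNA to KIAA1328 (-0.84) and CTDP1 to PARD6G (-0.85). The longest of the 13, SLC25A5-AS1 to MBNL3, held 38 genes with a median of -0.715, and 5 were at least 2-fold lower. Low levels were thus not limited to the genes around SMAD4, and these stretches need not be independent of each other. Some other stretches held families of related genes, such as the SPRR and S100 genes in HPDE or the CXCL genes in SU86.86.

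A difference in DNA copy number may underlie some of these stretches, a hypothesis that expression alone cannot settle because no DNA was measured here. In SU86.86 the 10 measured genes nearest to CDKN2A on chromosome 9 had a median of -0.66, below all random sets, with 7 lower, 4 of them by 2-fold or more. The medians of its sides were -1.55 (percentile 0) and -0.36 (percentile 3.94). The pooled median ran from -0.25 to -1.31 over the settings tried, which is consistent with a loss around the gene. Genes near CDKN2A belong to the stretch found by the scan and are not independent evidence. In PANC1 the same 10 genes had a median of -0.26 (percentile 2.63), with 9 lower but 1 by 2-fold or more. The medians of the sides of CDKN2A were -0.024 (percentile 41.83) and -0.86 (percentile 0.31) in PANC1. The pooled median ran from -0.081 to -0.57 over the settings, and MTAP stood at 9.83. A loss limited to CDKN2A and CDKN2B, a wider loss and silencing therefore cannot be told apart. For AKT2 in PANC1 on chromosome 19 the 20 nearest genes had a median of 0.0024 (percentile 49.4), with 10 higher and 10 lower, which decides nothing. The 10 genes on a single side had a median of 1.33 and those on the other -0.25. A gain that ends near AKT2 stays open, and the high side belongs to the stretch found by the scan and is not independent evidence.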
